A study of Homo sapiens with 48 samples.

How the data were processed

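Total RNA from 48 samples of the human leukaemia lines MOLM13 and MV411 was sequenced after removal of ribosomal RNA, as strand-specific paired-end libraries. Per the submitters' protocol, cells with a control or a CIITA sgRNA were treated for 72 h with DMSO, decitabine at 100 nM, recombinant IFNγ at 100 ng/ml or both drugs, and a part of each culture was harvested. Per the submitters' processing notes, reads were processed with STAR 2.3.0e, Picard 1.63 and R 3.3.0 against hg38. The deposited files hold 1 count per gene, as whole numbers with no normalization, per the file headers, for 60623 genes with their exon coordinates. The position of 99.98% of the 58516 identifiers found in GENCODE overlapped the reference annotation, and 79.7% had the same start and end. In 333 genes nested in a gene of the other strand the median ratio of count density between inner and outer gene was 1.088, with 9 below 0.05, so the counts ignore strand although the libraries keep it. Genes that overlap on either strand therefore share reads. Of the genes named, 17 share at least 10% of their exon bases with 1 other gene, namely ALDH1A3, CD48, CIITA, CTSD, DEXI, FAS, HLA-B, HLA-DOB, HLA-F, HSPA1B, ICAM1, IFI30, IRF9, MEF2C-AS2, RAET1E, TAP1 and TNFRSF10C, by 11.1% (MEF2C-AS2) to 42.5% (IFI30). All values given for them are uncertain, and the share of exons does not bound the share of counts, since RAET1E had a mean of 11 counts against 588.6 in its partner and HLA-DOB 605.9 against 3625.

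Each library was assigned to a line, an sgRNA, a treatment and a replicate number from its labels, which gave 16 groups of 3. The source name of the 24 MV411 libraries reads MOLM13, in conflict with their titles and cell line field; the titles and field were used. Library totals ran from 35959001 to 62797444 counts. No file was left out. HLA-DRB3 and HLA-DRB4 were not analysed here, since the files carry no such genes. Within the groups the 48 pairs of replicates held 0 identical pairs, and their counts differed by 3.37 to 36.7 times the variance of counting alone (median 12.1), so no replicate was a resequenced copy of another.

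Counts were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). Genes with low counts were removed with filterByExpr, libraries were scaled with the trimmed mean of M-values (TMM), and a quasi-likelihood negative binomial model was fitted per line over its 24 libraries with 1 term per group. This left 26267 genes in MOLM13 and 27591 in MV411. The biological coefficient of variation was 7.36% in MOLM13 and 7.59% in MV411, and the scaling factors ran from 0.943 to 1.085 and from 0.901 to 1.071. Differences between the lines were tested in a fit of the 12 control sgRNA libraries that each treatment effect uses. P-values were adjusted with the Benjamini-Hochberg method over all genes of a comparison, and 0.05 was the limit. Standard errors were computed as the log2 fold change over the square root of the quasi-likelihood F. The 23 comparisons were each treatment against DMSO and the combination against IFNγ in control sgRNA cells, the decitabine by IFNγ interaction, the CIITA against the control sgRNA in each treatment, the sgRNA by combination interaction, and the line differences in the 3 treatment effects.

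The comparisons, the alternatives and the gene lists were fixed before the data were examined. The lists covered HLA class II genes, class II regulators, class II processing, HLA class I, IFNγ response, type I interferon, checkpoint and costimulation, NK ligands, inflammatory genes of NF-κB, monocyte and macrophage, progenitor and granule, erythroid and megakaryocytic, lymphoid, cell cycle, p53 targets, DNA methylation machinery, cancer-testis and germline, genes near CIITA, and stress and RNA quality, 19 lists in all. They were written from general knowledge and not from these libraries, and many overlap in function. Each was compared with the other genes by camera with a preset correlation of 0.01, and again with a correlation estimated from the libraries. Counts of list members past the test are given over all genes and, for some lists, also adjusted over the list alone. The genes named were chosen by a rule fixed at the same time, namely CIITA and the measured class II genes, the 5 largest rises and falls among genes past the test whose replicates did not overlap and whose mean was at least 1 CPM in the higher group, and up to 4 members of each other list by size of change. The text names part of the genes so chosen.

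Where a group had 0 counts for a named gene, the fold was bounded with a floor of 3 counts over the group, which is 0.019 to 0.025 CPM. The count of the other group was taken as observed. A fold given as at least a value therefore leaves out the counting error of that other group. With 1 to 3 counts the ratio is given with an exact 95% Clopper-Pearson interval from the counts. Genes of the sex chromosomes that reveal a sex are not reported here.

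The alternatives were scaling with DESeq2 size factors in edgeR, no filter beyond 1 count in any library, a filter at 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, other libraries in the fit (the compared groups alone, or all 48 for the line differences), the replicate number as a block, and each library of a comparison left out in turn. For the CIITA sgRNA in MV411 with IFNγ, leaving out 2 libraries with over 8% of counts in miscellaneous RNA, and that share as a covariate, were added after the data were seen. Replicate numbers were taken as pairing the libraries of a comparison when all same-number pairs had a residual correlation above 0.1, which held for decitabine, IFNγ and the sgRNA comparison in DMSO in both lines, and in MOLM13 also for the combination against IFNγ and the sgRNA comparisons with IFNγ and with the combination. The test was tried on data simulated for MOLM13 decitabine against DMSO, where it called 77.6% of 67 genes changed by 1.5-fold, 97% of 67 changed by 2-fold, 100% of 66 changed by 4-fold and 14 of the unchanged genes, against 25 with DESeq2. The changed genes were drawn only from those with an average above 1 CPM, so these shares do not hold for genes of lower level. The libraries were simulated as independent, without the correlation of same-number replicates. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.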

Results

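A total number of 48 RNA sequencing libraries was analysed, from 16 groups of 3 replicates. MOLM13 and MV411, human acute myeloid leukaemia cell lines of monocytic character, carried either a control single guide RNA (sgRNA) or an sgRNA against CIITA, the gene of the master transactivator of HLA class II. Each of these 4 cell populations received DMSO, decitabine (100 nM, an inhibitor of DNA methyltransferases), interferon gamma (IFNγ, 100 ng/ml) or the combination for 72 h. The deposited files gave counts for 60623 genes, of which 52539 had at least 1 count. Library totals ran from 35959001 to 62797444 counts. Protein-coding genes took 73.35% to 83.44% of the counts, and this share moved with treatment. In control sgRNA cells of MOLM13 it was 79.3% ± 1.9 in DMSO, 77.4% ± 0.26 with decitabine, 76.9% ± 1.85 with IFNγ and 74.8% ± 0.38 with the combination, while the miscellaneous RNA class went from 6.64% ± 0.87 in DMSO to 9.0% ± 0.26 with the combination. In those of MV411 the protein-coding share was 82.3% ± 1.94, 81.8% ± 1.23, 79.4% ± 2.21 and 76.3% ± 1.39 in the same order, and miscellaneous RNA went from 5.18% ± 1.19 to 8.21% ± 0.86. Levels are given as counts scaled to a common library size (CPM, mean ± SD, n = 3), and changes as log2 fold changes ± standard error with 3 libraries per group. Adjusted p-values are Benjamini-Hochberg values over all genes tested with edgeR's quasi-likelihood test. No label states that the replicates came from separate cultures, so p-values measure the spread between these libraries only.

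CIITA itself (ENSG00000179583, chromosome 16, 10866222 to 10943021, hg38) was read in every group. In MOLM13 with the control sgRNA its level was 24.3 ± 1.52 CPM in DMSO, 31 ± 1.22 with decitabine, 137 ± 12.7 with IFNγ and 161 ± 3.64 with the combination. MV411 started higher, with 80.3 ± 3.49 CPM in DMSO, 83.1 ± 2.41 with decitabine, 206 ± 9.01 with IFNγ and 212 ± 4.77 with the combination. In the cells with the CIITA sgRNA the levels in the same order were 25.8 ± 1.26, 30.6 ± 1.81, 138 ± 10.1 and 173 ± 7.87 CPM in MOLM13. They were 89 ± 6.9, 95.1 ± 0.63, 212 ± 10.6 and 226 ± 6.49 CPM in MV411. The CIITA transcript did not pass the test between the sgRNAs in any of the 8 line and treatment pairs. In MV411, however, each CIITA sgRNA library had more of it than each control library in DMSO, with decitabine and with the combination. Within 1 treatment 3 against 3 libraries do not overlap, in either direction, in 10% of cases by chance. The chance of the same direction in 3 of 4 treatments is lower and was not computed. The log2 fold changes of CIITA in the order DMSO, decitabine, IFNγ and combination were 0.08, -0.02, 0.01 and 0.11 in MOLM13, and 0.15, 0.20, 0.04 and 0.09 in MV411. Small insertions or deletions at the cut site can leave the transcript in place, so its level neither shows nor excludes a loss of the protein. Part of the CIITA exons overlaps DEXI on the other strand, and the deposited counts ignore strand.

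**Figure D1:**
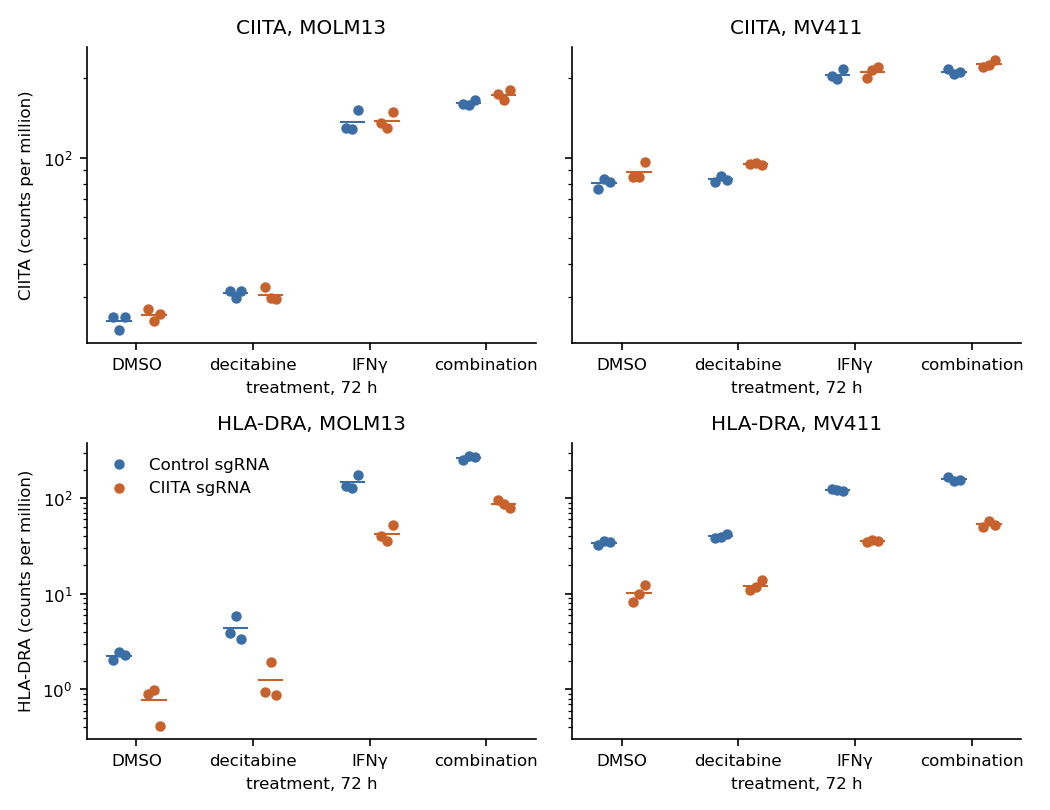
CIITA and HLA-DRA in CPM (log axis) in each of the 48 libraries, by treatment, line and sgRNA; horizontal lines are means of 3 libraries. CIITA does not pass the test between the sgRNAs, and in MV411 its CIITA sgRNA libraries lie above the control ones in 3 of the 4 treatments, whereas HLA-DRA lies lower in every CIITA sgRNA group than in its control.

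With IFNγ or the combination most class II genes passed the test as lower in MOLM13 cells with the CIITA sgRNA. In DMSO 0 passed with edgeR, although each CIITA sgRNA library there had less HLA-DRA than each control library (log2 fold change -1.57). HLA-DRA (ENSG00000204287, chromosome 6, 32439878 to 32445046), which encodes the invariant alpha chain of HLA-DR, reached 146 ± 26.9 CPM with IFNγ in control cells and 42.6 ± 8.56 CPM in CIITA sgRNA cells, a log2 fold change of -1.77 ± 0.15 (adjusted p = 4.8e-08). With the combination the levels were 266 ± 12.2 and 87.2 ± 8.17 CPM (-1.61 ± 0.14, adjusted p = 1.6e-07). HLA-DPA1 (ENSG00000231389, chromosome 6, 33064569 to 33080775), the alpha chain of HLA-DP, fell by 1.80 on the log2 scale with IFNγ and by 1.52 with the combination. HLA-DRB1, which pairs with HLA-DRA, changed by -1.72 with IFNγ, and HLA-DMA, which helps load peptides, by -0.97. CD74 (ENSG00000019582, chromosome 5, 150400041 to 150412929), the invariant chain that occupies the peptide groove, changed by -0.97 ± 0.07 with IFNγ and -0.97 ± 0.07 with the combination. HLA-DRB1, HLA-DRB5 and HLA-DRB6 are near-identical paralogs whose counts may share reads, so their separate values are uncertain.

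In MOLM13 with IFNγ 13 genes were lower and 0 higher with the CIITA sgRNA, 10 of them class II genes of the 12 tested (10 adjusted over the list alone, median -1.45, camera adjusted p = 2.6e-08 with an estimated correlation). Without the first CIITA sgRNA replicate with IFNγ, 7 genes passed. With the combination 12 genes were lower and 1 higher, and 10 of the 12 class II genes were among the lower (11 adjusted over the list alone, median -1.54, adjusted p = 3.1e-08 with an estimated correlation). The higher gene was MT-RNR2 (log2 fold change 4.03 ± 0.77, adjusted p = 0.037), a mitochondrial ribosomal RNA that library preparation removes, which ranged from 3.54 to 39.0 CPM among the CIITA sgRNA libraries. Its call was lost without the second CIITA sgRNA replicate with the combination (2.79, adjusted p = 0.863), without any 1 of the control replicates there (adjusted p from 0.225 to 0.419) and with the CPM filter (0.0664). With decitabine HLA-DRA was the 1 gene past the test (-1.85 ± 0.27, adjusted p = 0.0065); leaving out the CIITA sgRNA replicate 1 or 3 or the control replicate 2 with decitabine left 0 genes. Without those libraries the adjusted p of HLA-DRA was 0.127, 0.297 and 0.132, and it was 0.0569 with the other groups left out of the fit. The class II list was lower there with 5 members adjusted over the list alone (median -0.55, or -0.33 with near-zero genes at their bound or ratio, adjusted p = 0.031 with an estimated correlation). In DMSO edgeR called 0 genes, with 812 at an unadjusted p under 0.05, while DESeq2 called 1, HLA-DRA (adjusted p = 0.0149). HLA-DRA stood at 2.26 ± 0.228 and 0.767 ± 0.306 CPM there (-1.57 ± 0.33, adjusted p = 0.867). The class II median in DMSO was -0.30, or -0.23 with the genes of 3 or fewer counts in a group at their bound or ratio, and its camera call was lost (adjusted p = 0.396 with an estimated correlation). For the sgRNA effect with the combination against that in DMSO, 1 gene passed, CD74 (-0.86 ± 0.10, adjusted p = 3.3e-05).

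In MV411 class II genes were lower with the CIITA sgRNA in all 4 treatments, DMSO included. HLA-DRA stood at 34.3 ± 1.91 CPM in control and 10.2 ± 2.15 CPM in CIITA sgRNA cells in DMSO, a log2 fold change of -1.75 ± 0.10 (adjusted p = 3.3e-12). The change was -1.71 ± 0.10 with decitabine, -1.77 ± 0.09 with IFNγ and -1.55 ± 0.09 with the combination. CD74 changed by -0.89 ± 0.07 in DMSO, -0.79 with decitabine, -1.10 with IFNγ and -0.98 with the combination. RFX5, which encodes a subunit of the factor that recruits CIITA to class II promoters, was slightly lower with IFNγ (-0.27 ± 0.05, adjusted p = 0.011), and so were the granule genes PRTN3 (-0.51) and AZU1 (-0.31). These 3 calls were lost without the second CIITA sgRNA replicate with IFNγ (adjusted p = 0.208, 0.121 and 0.198), the third (0.0627, 0.0694 and 0.119) or the first control replicate (0.0879, 0.0774 and 0.114), and with the other groups left out of the fit (0.325, 0.0831 and 0.382). Those of RFX5 and AZU1 were also lost without the second control replicate (0.0623 and 0.0639), and that of RFX5 without the third (0.0629). Of the 6 libraries compared with IFNγ, the first CIITA sgRNA replicate and the second control replicate had 8.88% and 8.44% of their counts in miscellaneous RNA, against 5.76% to 5.99% in the other 4. Without both, an alternative chosen after the data were seen, PRTN3 and AZU1 passed and RFX5 did not (-0.27, adjusted p = 0.0997).

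Of the 12 class II genes tested in MV411, 9 were lower in DMSO, 9 with decitabine, 10 with IFNγ and 10 with the combination; adjusted over the list alone there were 10, 10, 11 and 10. The list medians were -1.34, -1.30, -1.50 and -1.31, and with an estimated correlation the adjusted p-values were 6.4e-13, 1.7e-13, 4.6e-14 and 4.3e-15. Over all genes 15 were lower and 2 higher in DMSO; with the replicate number as a block 93 genes passed. Without the second control DMSO replicate 65 passed, without the first 11, and without the first CIITA sgRNA DMSO replicate 10. The 2 higher genes were NTNG2, an axon guidance ligand (0.58), and SYT11, a vesicle protein gene (0.54); neither passed when the other groups were left out of the fit (adjusted p = 0.282 and 0.374) or without the first or second CIITA sgRNA DMSO replicate (0.0683 and 0.0674 for NTNG2, 0.13 and 0.0931 for SYT11); NTNG2 was also lost without the third control replicate (0.15) and SYT11 without the first or second (0.0855 and 0.0804). With decitabine 15 genes were lower and 0 higher, the lower ones with CD38 (-0.35), a surface enzyme of immune cells. CD38 did not pass without the CIITA sgRNA replicates 1 or 2 or the control replicates 1 or 3 with decitabine (adjusted p = 0.0711, 0.158, 0.0526 and 0.107). DESeq2 called 41 there, 12.2% of them higher. With IFNγ 42 were lower and 3 higher, among these the long non-coding MEF2C-AS2 (0.41) and PCNX1 (0.28), a membrane protein gene. Neither passed without the second CIITA sgRNA IFNγ replicate (adjusted p = 0.181 and 0.0801) or with the other groups left out of the fit (0.382 and 0.194), and MEF2C-AS2 held in 1 of 6 fits that left out a library. That count depended on single libraries, with 82, 15 and 21 genes without the CIITA sgRNA IFNγ replicates 1, 2 and 3, and 23 and 26 without the control IFNγ replicates 1 and 2. Without the first CIITA sgRNA and the second control replicate together, those rich in miscellaneous RNA, it was 21 (2 higher and 19 lower), and MEF2C-AS2 (adjusted p = 0.0605) and PCNX1 (0.0735) did not pass; with that share as a covariate it was 95 (18 higher and 77 lower). DESeq2 called 98, 18.4% of them higher against 6.7% with edgeR. With the combination 17 were lower and 2 higher, MAGED1 (1.00), a melanoma antigen family gene, and DPYSL2 (0.27), a cytoskeletal regulator; DESeq2 called 38, 34.2% of them higher against 10.5%, and without the third CIITA sgRNA combination replicate 12 passed. The MAGED1 call was lost without the second control combination replicate (adjusted p = 0.0684), and that of DPYSL2 in 5 of 6 fits that left out a library (0.0824 to 0.28) and with the other groups left out (0.0754). For the sgRNA effect with the combination against that in DMSO, edgeR called 0 genes, with 1464 at an unadjusted p under 0.05, and DESeq2 0. The type I interferon genes had a median of -0.76 in DMSO with 0 members past the test and 33 lower adjusted over the list alone (adjusted p = 0.092 with an estimated correlation).

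Decitabine lowered the basal interferon-stimulated transcripts of MOLM13, and S100A9, S100A8 and 4 of 12 class II genes rose, the latter in a list whose call was lost (adjusted p = 0.109 with an estimated correlation). OAS2 (ENSG00000111335, chromosome 12, 112978395 to 113011723), an antiviral sensor of double-stranded RNA, went from 5.56 ± 0.772 to 0.187 ± 0.135 CPM, a log2 fold change of -4.93 ± 0.39 (adjusted p = 5.3e-09). IFIT1, an antiviral RNA-binding gene (-4.21 ± 0.22), IFI44L (-4.23 ± 0.58) and EPSTI1 (-3.76 ± 0.41), both interferon-induced, and SIGLEC1, a macrophage lectin (-3.50 ± 0.61), fell likewise, and IRF9, part of the type I interferon transcription factor, changed by -1.09. CXCL10, a chemokine that IFNγ and type I interferon share, changed by -2.56 ± 0.50. S100A9 (ENSG00000163220, chromosome 1, 153357854 to 153361023) rose by 3.54 ± 0.52 and its partner S100A8 by 3.14 ± 0.42; together they form calprotectin. Among the class II genes HLA-DRA rose by 0.94 ± 0.24 from 2.26 ± 0.228 to 4.38 ± 1.33 CPM (adjusted p = 0.013), HLA-DQB1 by 1.72 ± 0.28, HLA-DMA by 0.86 ± 0.14, CD74 by 0.34 and CIITA by 0.35 ± 0.07 (adjusted p = 0.0016). HLA-DQB1 overlaps an antisense gene, which leaves its value uncertain.

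Of 26267 genes tested, 1218 were higher and 823 lower with decitabine in MOLM13. The replicate numbers paired these libraries, and with the number as a block 3118 genes passed. Without decitabine replicate 1 the total was 1048 and without replicate 3 it was 1325. The HLA-DRA call was lost without decitabine replicate 2 (log2 fold change 0.68, adjusted p = 0.107) and without DMSO replicate 1 (0.86, adjusted p = 0.0577). Other rises were GNLY, a cytolytic granule gene (2.67), PLAAT3, a phospholipase (3.02), TCN2, a vitamin transporter (2.54), CEBPE, a granulocyte transcription factor (1.58), and the granule genes MPO (1.45) and ELANE (0.66). The lysosomal protease CTSD rose by 0.79, the lysosomal reductase IFI30 by 0.60 and HLA-B by 0.36. Of the p53 targets EDA2R (1.17), GDF15 (1.10) and ZMAT3 (0.81) were higher, in a list whose call was lost (adjusted p = 0.059 with an estimated correlation). The costimulatory ligands CD86 (1.17) and TNFSF4 (0.99) rose and the adhesion gene ICAM1 fell by 0.69 on the log2 scale. DNMT3B (-0.40) and DNMT3A (-0.21), the de novo DNA methyltransferases, were lower. The germline genes TKTL1 (1.86) and TDRD9 (1.22) were higher. Chemokines moved apart, with CCL4 at -2.48 and CCL2 at 1.47, and of the stress genes HMOX1 rose by 1.16 while TRIB3 changed by -0.72. The NK ligand RAET1E (-1.12) and the T cell receptor constant gene TRAC (-0.90) were lower and CD48, an adhesion ligand of lymphocytes, was higher (0.54). FCN1, a monocyte lectin, had 0 counts over the DMSO libraries and 31 over the decitabine libraries, at least 12.4-fold higher against a floor of 3 counts over the group. In the 6 fits that left out a library some calls were lost. DNMT3A held only without DMSO replicate 3 (log2 fold changes from -0.24 to -0.19, adjusted p up to 0.168), RAET1E only without DMSO replicate 2 (from -1.31 to -0.96, up to 0.17, and 0.0511 with DESeq2) and CCL4 only without decitabine replicate 1 or DMSO replicate 3 (from -3.28 to -2.04, up to 0.163). GDF15 was lost without decitabine replicate 3 (0.86, adjusted p = 0.183) or DMSO replicate 1 (0.97, 0.117) or 3 (1.01, 0.105), TNFSF4 and DNMT3B without decitabine replicate 3 (0.94, 0.0591 and -0.39, 0.0641) or DMSO replicate 1 (0.81, 0.0891 and -0.31, 0.115), TKTL1 without decitabine replicate 1 (1.31, 0.141) or DMSO replicate 3 (1.52, 0.0652), and HMOX1 without decitabine replicate 1 (0.95, 0.0728).

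Across the lists in MOLM13, 29 of 35 type I interferon genes were lower and 0 higher with decitabine (31 lower adjusted over the list alone, median -1.26), the list whose camera call held (adjusted p = 8.6e-05 with an estimated correlation). Monocyte and macrophage genes numbered 12 higher and 2 lower of 25 (15 higher adjusted over the list alone, adjusted p = 0.071 with an estimated correlation), and p53 targets 17 higher of 29 (22 alone, adjusted p = 0.059 with an estimated correlation). For class II genes 4 of 12 were higher (7 adjusted over the list alone) with a median of 0.97, or 1.02 with near-zero genes at their ratio (adjusted p = 0.109 with an estimated correlation). Class II processing genes counted 5 of 10 higher (adjusted p = 0.109 with an estimated correlation) and class I genes 7 of 22 (adjusted p = 0.11 with an estimated correlation). NK ligands counted 1 higher and 4 lower of 12 (adjusted p = 0.133 with an estimated correlation). IFNγ response genes counted 1 higher and 12 lower of 45, checkpoint and costimulation genes 4 and 2 of 19, inflammatory genes 2 and 7 of 21, progenitor and granule genes 6 and 3 of 17 (camera adjusted p = 0.539 with an estimated correlation; with the preset correlation 0.112, and 0.0172 with the replicate number as a block). Methylation machinery genes counted 0 higher and 3 lower of 15, cancer-testis genes 2 and 0 of 13, stress genes 3 and 2 of 16, lymphoid genes 2 and 1 of 9, and class II regulators, CIITA among them, 1 and 1 of 8. Of 36 cell cycle genes, 7 erythroid and megakaryocytic genes and 8 genes near CIITA, 0 passed with edgeR in each list.

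MV411 lost the same kind of transcripts with decitabine, while its class II genes moved little. OAS3, an antiviral enzyme of the OAS2 family (ENSG00000111331, chromosome 12, 112938444 to 112973251), changed by -3.38 ± 0.46 (adjusted p = 8.3e-05), IFI44L by -3.29 ± 0.46, IFI44 by -3.26 ± 0.48, CXCL10 by -3.24 ± 0.66, SIGLEC1 by -2.78 and the antiviral GTPase MX1 by -3.00 ± 0.42. HLA-DRB1 rose by 0.44 ± 0.07 and HLA-DPA1 by 0.28 ± 0.06 (adjusted p = 0.0097). HLA-DRA changed by 0.22 ± 0.09 (adjusted p = 0.219) and CIITA by 0.05 ± 0.05 (adjusted p = 0.766), and neither passed. The largest rises were ranked among genes past the test whose replicates did not overlap and whose mean was at least 1 CPM in the higher group. They were GPRIN3, a neurite outgrowth gene (1.99 ± 0.25), ALDH1A3, a retinoic acid synthesis enzyme (1.52 ± 0.08), which overlaps another gene over part of its exons, MNDA, a myeloid nuclear antigen (1.45 ± 0.30), TKTL1 (1.44 ± 0.32), and GATA2, a stem cell transcription factor (1.39 ± 0.33). Without DMSO replicate 3 the calls of HLA-DPA1 (adjusted p = 0.0523), TKTL1 (0.0735) and GATA2 (0.0925) were lost, without decitabine replicate 1 those of TKTL1 (0.0819) and GATA2 (0.131), and without DMSO replicate 2 that of GATA2 (0.0888). HLA-DPA1 also did not pass with the other groups left out of the fit (0.0803).

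Of 27591 genes tested in MV411, 389 were higher and 311 lower with decitabine; with the replicate number as a block 1443 passed. Without decitabine replicate 1 the total was 348, without replicate 3 it was 420, and without DMSO replicate 2 or 3 it was 450 or 372. The class I transactivator NLRC5 (0.29), the signalling inhibitor SOCS1 (0.73), the integrin ITGAM (1.02), GNLY (2.96), PRTN3 (0.56) and the p53 target FDXR (0.51) were higher. The GNLY call was lost without decitabine replicate 2 (adjusted p = 0.0761) or DMSO replicates 1 or 3 (0.0595 and 0.0538). MAGEA4, a cancer-testis antigen, had 0 counts over the DMSO libraries and 56 over the decitabine libraries, at least 23.3-fold higher. ETV7, an interferon-induced repressor, had 38 counts in DMSO and 3 with decitabine, 10.1-fold lower (95% counting interval 3.22 to 51.4). Intervals cover counting error only, and floors only that of the group with 0 counts. Type I interferon genes were lower for 33 of 35 (35 adjusted over the list alone, median -1.35, adjusted p = 0.007 with an estimated correlation). Class II genes were higher for 3 of 12 (5 alone, median 0.20, adjusted p = 0.023 with an estimated correlation). The cancer-testis list had 2 higher of 12 (adjusted p = 0.071 with an estimated correlation) and cell cycle genes 0 of 36 (adjusted p = 0.86 with an estimated correlation). Between the lines, which share no libraries, 139 genes were higher and 107 lower with decitabine in both, where independent lists would share 17.0 and 9.57.

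**Figure D2:**
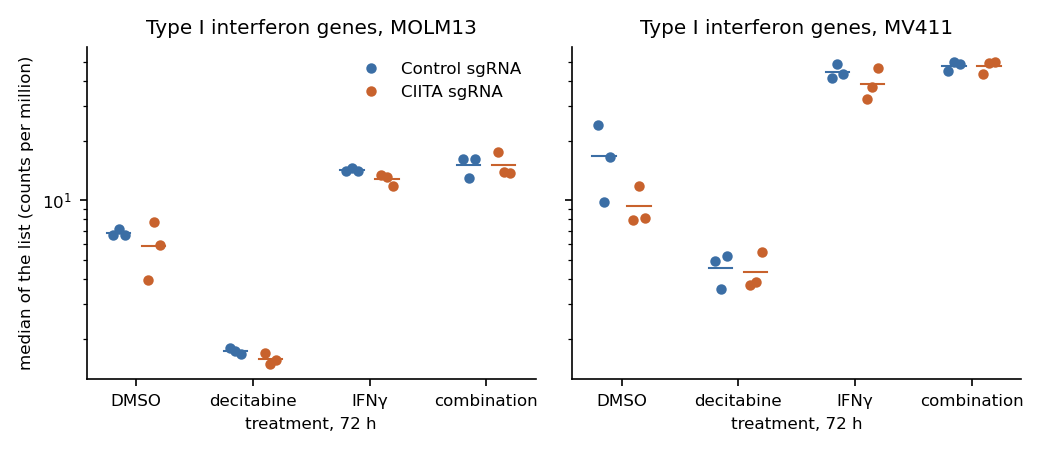
Median of the type I interferon genes in CPM (log axis) in each library, by treatment, line and sgRNA; horizontal lines are means of 3 libraries. In MOLM13 the control sgRNA libraries lie from 6.69 to 7.19 in DMSO and from 1.67 to 1.79 with decitabine, and in MV411 from 9.76 to 24 and from 3.56 to 5.24.

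IFNγ induced the class II genes of MOLM13, some from near zero, as HLA-DPA1 at 0.0699 ± 0.024 CPM in DMSO, while HLA-DOB (11.2 ± 0.338 CPM) and CD74 (119 ± 6.19 CPM) started higher. HLA-DRA went from 2.26 ± 0.228 to 146 ± 26.9 CPM, a log2 fold change of 6.01 ± 0.20 (adjusted p = 2.4e-19), and CIITA rose by 2.49 ± 0.07 (adjusted p = 7.4e-21). HLA-DPA1 rose by 6.29 ± 0.32, HLA-DRB1 by 5.80 ± 0.21, HLA-DMA by 3.28, CD74 by 2.53 ± 0.07 and HLA-DOB, a modulator of peptide loading that overlaps a readthrough of TAP2, by 1.44. HLA-DQA1 had 2 counts over the DMSO libraries and 155 with IFNγ, 89.1-fold higher (24.2 to 742). GBP1, an interferon-induced GTPase, had 2 and 11764 counts, 6760-fold higher (1870 to 55800), and SERPING1, a complement inhibitor, had 3 and 5258, 2010-fold higher (689 to 9770). CD274 (ENSG00000120217, chromosome 9, 5450503 to 5470566), the checkpoint ligand PD-L1, rose by 7.06 ± 0.24, the costimulatory receptor CD40 by 4.41 and PDCD1LG2, the PD-L2 gene, by 3.65. ETV7 (9.65 ± 0.14), GBP4 (7.81) and the complement gene C4B (8.13) were among the largest rises; C4B has a near-identical paralog, which leaves its value uncertain.

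In MOLM13 3455 genes were higher and 2842 lower with IFNγ. The largest falls included HS3ST1, a heparan sulfate enzyme (-4.12), F13A1, a coagulation factor (-4.02), and TOX, a transcription factor of lymphocytes (-3.91). The peptide transporter TAP1 (4.36), which overlaps an antisense gene, the immunoproteasome gene PSMB9 (3.96), HLA-F (3.80), IFI30 (3.33), ICAM1 (2.50) and the type I interferon gene IFI27 (5.92) rose. Monocyte receptors CD14 (3.20) and CLEC7A (2.82) were higher. The stem cell receptor KIT (-2.33), the granule protease CTSG (-1.38), the demethylase TET1 (-2.15), DNMT3B (-0.88), the mitotic kinesin KIF11 (-0.54), the T cell gene CD3D (-3.21) and CCL2 (-2.28) were lower. Beside CIITA on chromosome 16, SOCS1 (2.23), RMI2 (1.24) and DEXI (0.57) were higher. The exons of DEXI overlap CIITA on the other strand over 36.2% of their bases, so its value, and its part in the list of genes near CIITA, is uncertain in counts that ignore strand. The death receptor FAS rose by 1.22. All 12 class II genes tested passed (median 5.46, adjusted p = 1.3e-05 with an estimated correlation). Likewise 45 of 45 IFNγ response genes (1.7e-10 with an estimated correlation), 20 of 22 class I genes (2.1e-09), 13 of 19 checkpoint and costimulation genes (9.1e-05), 8 of 10 processing genes (0.0073), 5 of 8 genes near CIITA (0.0067) and 22 of 35 type I genes (0.037) were higher. Type I genes moved both ways, as at least 5 had a lower mean level with IFNγ than in DMSO. In the CIITA sgRNA cells 21 of the 35 type I genes were higher and 5 lower with IFNγ. The cell cycle list was lower for 19 of 36 (adjusted p = 0.624 with an estimated correlation). For the class II regulators the median was -0.02, the mean 0.25 and the camera direction upward (adjusted p = 0.286 with an estimated correlation).

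MV411 responded to IFNγ with smaller class II changes from a higher start. HLA-DRA rose by 1.83 ± 0.09 (adjusted p = 1.5e-15) from 34.3 ± 1.91 to 122 ± 3.19 CPM, HLA-DPA1 by 2.46 ± 0.06, CD74 by 1.09 ± 0.07 and CIITA by 1.36 ± 0.05 (adjusted p = 2.9e-17). GBP1 rose by 11 ± 0.16, the chemokine CXCL9 by 8.62, GBP5 by 8.57, CD274 by 7.05 ± 0.16, TAP1 by 3.90, NLRC5 by 2.60 and MNDA by 3.15. F13A1 (-5.63 ± 0.35), the synaptic adhesion gene CLSTN2 (-4.54), the leukocyte receptor CD84 (-4.14), the adhesion gene NCAM1 (-3.98), KIT (-3.31) and CTSG (-2.92) fell. C1QB, a complement gene of macrophages, had 0 counts in DMSO and 246 with IFNγ, at least 95.7-fold higher.

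Of 27591 genes tested in MV411, 4812 were higher and 4671 lower with IFNγ. Class II genes were higher for 11 of 12 (median 1.74, adjusted p = 5.9e-08 with an estimated correlation), IFNγ response genes for 42 of 44 (1.3e-08), class I for 21 of 22 (9.8e-06), checkpoint for 10 of 19 (2.5e-04), processing for 8 of 10 (0.0091) and genes near CIITA for 4 of 8 (0.0018). The cell cycle list was lower for 27 of 36 (adjusted p = 0.072 with an estimated correlation), and 25 of 35 type I genes were higher (adjusted p = 0.192 with an estimated correlation). Both lines shared 2111 higher and 1625 lower genes, against 607 and 463 for independent lists.

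**Figure D3:**
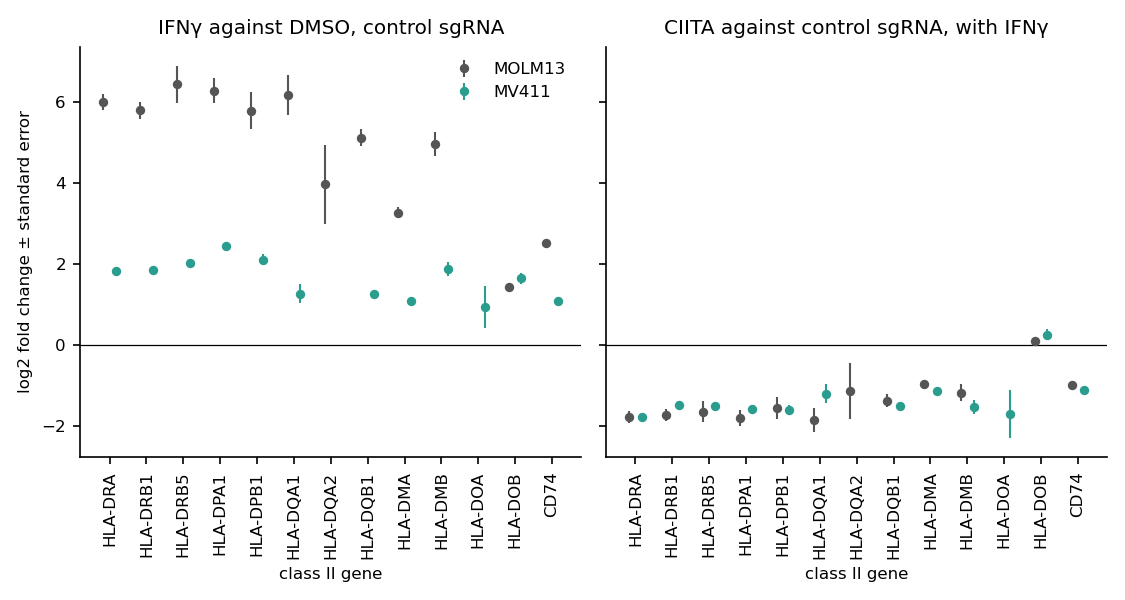
Log2 fold changes ± standard error of the class II genes in both lines, with IFNγ against DMSO in control sgRNA cells (left) and with the CIITA against the control sgRNA in the presence of IFNγ (right); genes not tested in a line have no point. HLA-DRA rises by 6.01 in MOLM13 and 1.83 in MV411 and differs by -1.77 between the sgRNAs in each line.

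Decitabine and IFNγ together raised the class II genes of MOLM13 above their DMSO level by more than IFNγ alone did. HLA-DRA rose by 6.88 ± 0.20 to 266 ± 12.2 CPM (adjusted p = 1.6e-20), HLA-DPA1 by 7.77 ± 0.29, CD74 by 2.90 and CIITA by 2.72 ± 0.07. HLA-DRB6, a class II pseudogene, had 0 counts in DMSO and 179 with the combination, at least 71.6-fold higher. ETV7 (9.60), CD274 (7.40), S100A9 (4.75 ± 0.49) and GNLY (3.32) rose, and the growth factor PDGFA (-4.77 ± 0.34), CD3D (-4.50), the angiopoietin gene ANGPT1 (-4.49) and HS3ST1 (-4.26) fell. In all, 5052 genes were higher and 4582 lower. All 12 class II genes tested were higher (median 6.45, or 6.53 with near-zero genes at their ratio, adjusted p = 8.7e-06 with an estimated correlation), as were 44 of 45 IFNγ response (2.5e-09), 21 of 22 class I (1.4e-08), 12 of 19 checkpoint (2.6e-04), 8 of 10 processing (0.005) and 6 of 8 genes near CIITA (0.012). Monocyte genes had 20 higher of 25 (adjusted p = 0.093 with an estimated correlation), p53 targets 22 of 29 (0.097) and type I genes 23 of 35 (0.093), whose calls were lost.

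In MV411 the combination raised HLA-DRA by 2.20 ± 0.09 (adjusted p = 3.5e-17) to 158 ± 7.03 CPM, HLA-DPA1 by 2.90 ± 0.06 and CIITA by 1.40 ± 0.05. MNDA (4.05), FAS (2.33) and the heat shock gene HSPA1B (1.64), which has a near-identical paralog, rose. NCAM1 (-3.67 ± 0.33), the lysosomal glycoprotein GPNMB (-3.50) and CLSTN2 (-3.38) fell. MAGEA4 had 0 counts in DMSO and 70 with the combination, at least 30.4-fold higher. There were 5433 higher and 5073 lower genes. Class II genes were higher for 11 of 12 (median 1.96, adjusted p = 1.2e-08 with an estimated correlation), IFNγ response for 42 of 44 (1.2e-08), class I for 21 of 22 (8.5e-06), checkpoint for 9 of 19 (6.1e-04), processing for 8 of 10 (0.029) and genes near CIITA for 4 of 8 (0.0081). The lines shared 2740 higher and 2297 lower genes, against 991 and 829 for independent lists.

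Decitabine added to IFNγ raised class II further in MOLM13. Against IFNγ alone HLA-DRA was higher by 0.86 ± 0.14 (adjusted p = 1.6e-04), HLA-DPA1 by 1.48 ± 0.17, HLA-DRB1 by 0.90, CD74 by 0.38 and CIITA by 0.23 ± 0.06 (adjusted p = 0.018). The CIITA call was lost without IFNγ replicate 1 (0.19, adjusted p = 0.115) or 2 (0.19, adjusted p = 0.119) and without combination replicate 3 (0.21, adjusted p = 0.076). S100A9 (2.23 ± 0.39), S100A8 (2.16), the B cell adaptor GAPT (2.31), the immunoglobulin transporter PIGR (2.23), the integrin ITGA9 (2.17), the inhibitory receptor LILRB2 (1.62), CEBPE (1.45), the tryptophan enzyme IDO1 (1.24) and the decoy receptor TNFRSF10C (1.39) were higher. PDGFA (-3.98 ± 0.35), the hypoxia-responsive MIR210HG (-2.59), the interleukin receptor IL2RB (-2.21) and the glycolytic enzyme ENO2 (-1.99) were lower. The test called 1575 genes higher and 1427 lower; the total was 1686 and 1844 without IFNγ replicates 1 and 2, and 1838 and 1839 without combination replicates 1 and 3. Class II genes were higher for 11 of 12 (median 1.04, adjusted p = 0.0089 with an estimated correlation). For monocyte genes (13 of 25 higher) the call was lost (adjusted p = 0.112 with an estimated correlation), as for p53 targets (16 of 29, 0.112).

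In MV411 HLA-DRA was higher by 0.38 ± 0.08 with the combination than with IFNγ (adjusted p = 0.007), HLA-DPA1 by 0.43 ± 0.05, HLA-DPB1 by 0.52, the peptide exchange gene HLA-DMB by 0.65 and HLA-DRB1 by 0.35. CIITA did not pass (0.04 ± 0.05, adjusted p = 0.788). The retinol dehydrogenase DHRS9 (2.58 ± 0.31), the reductase MSRB3 (1.78), the phosphatase PTPRO (1.51) and ALDH1A3 (1.50) were higher, and the lectin CLEC10A (-1.46), the receptor SLAMF7 (-1.42), PDGFA (-1.41) and the chemokine CXCL8 (-1.31) lower. There were 811 higher and 615 lower genes; the total was 804 and 926 without combination replicates 2 and 3 and 888 without IFNγ replicate 1. The HLA-DMB call was lost without combination replicate 3 (adjusted p = 0.0564), that of SLAMF7 without IFNγ replicate 3 (0.0883), that of PTPRO without combination replicate 1 or IFNγ replicates 2 or 3 (0.0586, 0.058 and 0.0725), and that of CXCL8 without any library but IFNγ replicate 1 (0.0646 to 0.127). Class II genes were higher for 5 of 12 (7 adjusted over the list alone, median 0.30, adjusted p = 0.0012 with an estimated correlation). Inflammatory genes were lower for 7 of 19 (adjusted p = 0.053 with an estimated correlation).

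The test of whether decitabine acts differently with and without IFNγ (a positive value means a less negative or more positive decitabine effect in the presence of IFNγ) called 38 genes in MOLM13 and 52 in MV411, with type I interferon genes among the positive ones in both lines. In MOLM13 OAS2 had an interaction of 4.89 ± 0.45 (adjusted p = 2.2e-07), the ferlin gene OTOF of 4.06, IFI44L of 3.98, SIGLEC1 of 3.94 and IFIT1 of 3.85 ± 0.29. Negative interactions were those of CYBB, an oxidase subunit (-1.31 ± 0.27), the acute phase gene ORM1 (-0.73) and the growth arrest gene GAS6 (-0.64), which overlaps its antisense gene. CYBB did not pass with DESeq2 or the CPM filter (adjusted p = 0.0724 and 0.0583). In the 12 fits that left out a library CYBB held in 3 (highest adjusted p = 0.167), ORM1 in 4 (0.123) and GAS6 in 6 (0.0734), and SIGLEC1 was lost without decitabine replicate 3 (0.0553); ORM1 did not pass with the other groups left out of the fit (0.0669). For CIITA the interaction was -0.12 ± 0.09 (adjusted p = 0.94) and for HLA-DRA -0.08 ± 0.28 (adjusted p = 0.991). Of the MOLM13 genes past the test 33 were positive and 5 negative. The type I list had 23 positive of 35 (30 adjusted over the list alone, median 1.28, adjusted p = 5.7e-06 with an estimated correlation), and 0 of 12 class II genes passed with edgeR. In MV411 26 genes were positive and 26 negative. IFI44L (3.47 ± 0.57, adjusted p = 0.0061), IFI44 (3.38), MX1 (3.22) and OAS3 (3.17) were positive, and CCL2 (-1.70 ± 0.33), CYBB (-1.35), the interferon-induced ANKRD22 (-0.94) and the calcium exchanger SLC8A1 (-0.89) negative. Of the 12 fits that left out a library, CCL2 held in 6 (highest adjusted p = 0.0941), CYBB in 2 (0.226) and SLC8A1 in 3 (0.209), while OAS3 was lost without decitabine replicate 2 (0.0746). CYBB did not pass with DESeq2 or the CPM filter (0.0653 and 0.0529), nor SLC8A1 with the other groups left out (0.109). CIITA stood at -0.01 ± 0.08 (adjusted p = 0.999). The MV411 total was 87 without DMSO replicate 2, 32 without DMSO replicate 3, 23 and 25 without decitabine replicates 1 and 2, 31 without IFNγ replicate 1 and 31 without combination replicate 3. There the type I list had 15 positive of 35 (34 adjusted over the list alone, median 1.38, adjusted p = 0.0066 with an estimated correlation) and the inflammatory list 2 negative of 19 (median -0.34, adjusted p = 0.049 with an estimated correlation).

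The lines differed in their treatment effects by the test of the difference (MV411 minus MOLM13). For IFNγ HLA-DRA differed by -4.17 ± 0.15 (adjusted p = 1.1e-11), HLA-DPA1 by -3.82 ± 0.28, CD74 by -1.42 and CIITA by -1.12 ± 0.10 (adjusted p = 1.7e-06). The phospholipid flippase ATP9A (7.55), the membrane repair gene DYSF (5.80) and the interleukin receptor IL2RA (3.60) had more positive effects in MV411, and the ephrin receptor EPHB2 (-4.88) a more negative one. Genes with 3 or fewer counts in a group, such as BCAR1, HGF and BTBD11, were among the largest differences and are given no value. Effects were more positive in MV411 for 993 genes and more negative for 1202. Of the class II genes 10 of 11 had smaller rises in MV411 (median -3.82, adjusted p = 3.2e-04 with an estimated correlation), while the IFNγ response list split into 10 and 13 of 45 (median -0.07, adjusted p = 0.818 with an estimated correlation). Checkpoint genes had 6 smaller of 19 (median -0.20, adjusted p = 0.047 with an estimated correlation).

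For decitabine the differences were smaller, with -0.28 ± 0.09 for CIITA (adjusted p = 0.142) and -0.70 ± 0.18 for HLA-DRA (adjusted p = 0.061), neither past the test. CD74 (-0.38 ± 0.09, adjusted p = 0.036), HLA-DQB1 (-1.42), HLA-DMA (-0.85), CEBPE (-1.50), MPO (-1.05), GDF15 (-1.34), CD86 (-0.88) and the nucleoside transporter SLC28A3 (-3.03) had smaller effects in MV411. ANGPT1 (2.47) and the signalling regulator RGS1 (2.31) had more positive ones. In all, 196 genes were more positive and 240 more negative in MV411, and the total was 271 without MOLM13 decitabine replicate 1 and 284 without MV411 decitabine replicate 3. The CD74 call held in 4 of the 12 fits that left out a library (adjusted p from 0.0167 to 0.122), that of CD86 in 2 (highest adjusted p = 0.132), that of GDF15 in 7 (0.0755) and that of MPO in 10 (0.0558), with 0.0602 for MPO in a fit of all 48 libraries. ANGPT1 was lost without MV411 decitabine replicate 1 (0.0885), and the HLA-DRA difference passed with DESeq2 (adjusted p = 0.00886), with no filter (0.000182), and without MOLM13 decitabine replicate 3 (-0.87, 0.0113) or MV411 DMSO replicate 1 (-0.75, 0.0482). The no-filter value is not read as stronger evidence than that of the main edgeR fit. The class II list had 3 smaller of 11 (4 adjusted over the list alone, median -0.80, adjusted p = 0.021 with an estimated correlation). For the combination HLA-DRA differed by -4.67 ± 0.10, CD74 by -1.76, CIITA by -1.32 ± 0.08, ATP9A by 6.04 and DYSF by 4.77; 2147 genes were more positive and 2454 more negative. There 11 of 12 class II genes had smaller rises in MV411 (median -4.58, adjusted p = 1.1e-06 with an estimated correlation).

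Of the 437 list tests, 152 passed with the preset correlation and 45 of these with an estimated correlation. The 45 were class II in all comparisons except decitabine in MOLM13, both decitabine by IFNγ interactions, the sgRNA comparison in MOLM13 with DMSO and both sgRNA by combination interactions. IFNγ response, class I, checkpoint, processing and the genes near CIITA held with IFNγ and the combination in both lines. Type I interferon held with decitabine and in its interaction in both lines and with IFNγ in MOLM13. The others were checkpoint in the line difference for IFNγ, the inflammatory list in the MV411 decitabine by IFNγ interaction and the IFNγ response list in the MV411 sgRNA by combination interaction (18 genes positive adjusted over the list alone, 0 over all genes, adjusted p = 0.046). In MV411 with DMSO the IFNγ response list had a median of -0.23 between the CIITA and the control sgRNA. Part of the last call may therefore come from the level in the control DMSO libraries, which was not tested.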

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

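The tests in this part were chosen after the result was seen, except the one on IFNγ-treated RNA in the DMSO libraries and the splits for the 4 interactions within a line.

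Type I interferon genes were lower with decitabine in both lines, by a median of -1.26 in MOLM13 and -1.35 in MV411. A single DMSO library with high interferon genes is argued against. Leaving out the DMSO library that moves the median most toward 0 left -1.16 in MOLM13 and -0.98 in MV411. A chance state of the control libraries as the whole cause is argued against by medians of -1.08 and -0.76 in the CIITA sgRNA libraries. These share no library with the control ones. In MV411 part of the fall may still come from such a state. There the type I list median in DMSO was 16.8 ± 7.12 CPM in control and 9.31 ± 2.16 CPM in CIITA sgRNA libraries. With decitabine it was 4.57 and 4.37 CPM. The MV411 decitabine by IFNγ and sgRNA by combination interactions use the same control DMSO libraries. IFNγ-treated RNA in the DMSO wells would have to make up 36% (MOLM13) and 28.2% (MV411) of the RNA for the median lower gene, whereas GBP1 counts allow at most 0.0514% and 0.0653%. A candidate explanation is that decitabine lowers a basal type I interferon signal of these cultures. Whether that signal arises in the cells, from the medium or from the vector that carries the sgRNA, and whether cell density or another effect of decitabine lowers it, was not tested.

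Class II genes were lower with the CIITA sgRNA while CIITA itself was not. Reads shared between near-identical class II genes are argued against by HLA-DRA, which has no such expressed copy and whose log2 fold change nearest to 0 over the 8 pairs was -1.55, and a library with the wrong sgRNA label by the 8 of 8 pairs in which each CIITA sgRNA library had less HLA-DRA than each control library. HLA-DRA stood at 27.7% to 34.1% of its control in the 8 pairs, and these ratios did not differ beyond their errors (heterogeneity p = 0.663, from a chi-square test on the fitted values). This is consistent with a fixed share of cells with working CIITA in the CIITA sgRNA cultures, and equally with a uniform partial loss of function or a CIITA-independent remainder that scales with induction. For CD74 the ratios did differ (chi-square heterogeneity p = 1.9e-40), and no count per cell was analysed here that could separate these cases.

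Class II genes rose less with IFNγ in MV411 than in MOLM13, by a median of -3.82. A weaker IFNγ response of MV411 as a whole is argued against by the IFNγ response list, whose median line difference was -0.07. Alleles that differ from the reference were examined with HLA-DRA, HLA-DMA, HLA-DMB and CD74, genes with few alleles. These also rose less in MV411, with a median difference of -2.62. A share of reads lost at an allele cancels in this difference if it is equal with and without IFNγ, so the test does not decide on alleles. Over the 10 class II genes past the test the lines differed by a median of 4.31 in DMSO and 0.41 with IFNγ, but with IFNγ 5 of the 10 lay more than 1 log2 unit apart, HLA-DMB at -1.41, HLA-DQA1 at 1.04, HLA-DPB1 at 2.16, HLA-DRB5 at 3.11 and HLA-DPA1 at 3.29. Of the genes with few alleles, HLA-DRA (-0.26), HLA-DMA (-0.42) and CD74 (0.04) lay within 1 unit with IFNγ, and HLA-DMB did not. Alleles may shift the levels of the other genes between the lines, which was not tested. Whether a higher level before IFNγ with a like level after it accounts for the pattern therefore stays open. The lines differ in origin and genotype as well, which stays open and untested.

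The further results here differed between the lines by the test of the difference, as MV411 minus MOLM13. The decitabine effect differed for 436 genes, the IFNγ effect for 2195 and the combination effect for 4601. For decitabine the log2 differences were -3.03 for SLC28A3, -1.50 for CEBPE, -1.42 for HLA-DQB1, -1.34 for GDF15, -1.05 for MPO, -0.88 for CD86, -0.85 for HLA-DMA, -0.38 for CD74, 2.31 for RGS1 and 2.47 for ANGPT1. Lists past camera with the preset correlation had medians of -0.80 (class II), -0.48 (processing), -0.09 (class I), -0.38 (monocyte), 0.19 (NK ligands) and -0.19 (p53 targets), of which class II held with an estimated correlation. For IFNγ the differences were -4.88 for EPHB2, -4.17 for HLA-DRA, -3.82 for HLA-DPA1, -1.53 for CTSG, -1.42 for CD74, -1.12 for CIITA, -0.44 for TAP1, 3.60 for IL2RA, 5.80 for DYSF and 7.55 for ATP9A. List medians were -3.82 (class II), -0.84 (monocyte), -0.20 (class I), -0.20 (checkpoint), -0.19 (p53 targets), -0.07 (class II regulators) and 0.24 (inflammatory), of which class II and checkpoint held with an estimated correlation. For the combination the differences were -4.87 for HLA-DPA1, -4.67 for HLA-DRA, -1.76 for CD74, -1.32 for CIITA, 4.77 for DYSF and 6.04 for ATP9A, with list medians of -4.58 (class II), -1.22 (monocyte), -0.35 (processing), -0.27 (class I), -0.25 (p53 targets) and -0.18 (checkpoint), of which class II held.

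Other splits of the same libraries into groups of the same size were tested for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Each other split also mixes libraries of both groups, so genes that respond widen the spread within its groups. Low counts in the other splits are therefore no support for the real ones, and no conclusion is drawn from them. The real split alone, 1 of 10, gave as many genes with decitabine (2041 in MOLM13 with a highest other of 0, and 700 in MV411 with 1), IFNγ (6297 and 9483, with 0 and 0), the combination (9634 and 10506, with 0 and 0), and the combination against IFNγ (3002 and 1426, with 0 and 10). The same held for the CIITA sgRNA with decitabine (1 and 15, with 0 and 0) and with the combination (13 and 19, with 0 and 0). For the CIITA sgRNA in MOLM13 with DMSO the real value was 0 and the highest other 2, so 10 of 10 were as large. With IFNγ in MOLM13 3 of 10 splits gave as many as the real 13, the highest 67. That split keeps 2 of the 3 same-number pairs together, and among the splits that part all 3 pairs, as the real split does, the highest other was 0, which points to a structure by replicate number. In MV411 with DMSO 2 of 10 gave as many as the real 17, the highest 33 also parting all 3 pairs. That split sets CIITA sgRNA replicates 1 and 3 and control replicate 2 against the rest. The type I interferon list median was 7.99, 8.14 and 9.76 CPM in these libraries and 11.8 CPM or more in each of the rest. The split thus follows the level of these genes, and the real count was 65 without control replicate 2. Whether that level accounts for either count was not tested. In MV411 with IFNγ 2 of 10 gave as many as the real 45, and the other gave 977, setting the first CIITA sgRNA replicate with the first and second control replicates against the rest. The first CIITA sgRNA and the second control replicate, on 1 side of that split, had 8.88% and 8.44% of their counts in miscellaneous RNA, and the other 4 libraries, the first control replicate among them, 5.76% to 5.99%. The split points to a structure of these libraries that the labels do not name, and the real count was 21 without those 2 libraries and 95 with the share of miscellaneous RNA as a covariate.

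For the interactions 60 of 200 splits were drawn. Of these 27 lean the real way in 1 arm and the opposite way in the other, so that they add the effects of both arms where the real contrast subtracts them, and a tally that they fill decides nothing about chance; leaving them out was chosen after the tally was seen. In the decitabine by IFNγ interaction 7 of 60 gave as many as the real 38 genes in MOLM13 (highest other 5143), and of the 33 that do not add them 2 did, the real one included, so chance is not excluded. In MV411 6 of 60 gave as many as the real 52 (highest other 2713), and of the 33 the real split alone. In the sgRNA by combination interaction 11 of 60 gave as many as the real 1 in MOLM13 (highest other 5), 6 of the 33 among them, and 60 of 60 as many as the real 0 in MV411 (highest other 85). For the line differences 3 of 60 gave as many as the real 436 with decitabine (highest other 1956), 4 of 60 as many as the real 2195 with IFNγ (highest other 8743) and 2 of 60 as many as the real 4601 with the combination (highest other 11780). The 6 other splits as large all add the effects of both lines, and of the 33 that do not, the real one alone was as large for each treatment. All these splits exchange treatment or sgRNA labels within an arm, which mixes the libraries compared there. They do not keep an effect that is equal in both arms. The tallies, with or without the 27, therefore cannot test an interaction or a line difference, and no conclusion is drawn from them.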

How the results depend on the processing

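The settings were planned, except 2 chosen after the results were seen for the CIITA sgRNA in MV411 with IFNγ, which gave 21 genes without the 2 libraries with over 8% miscellaneous RNA and 95 with that share as a covariate. The cause of a change was not tested unless one is named. The planned change of pseudocount was not run, since the files hold counts. The counts for IFNγ and the combination against DMSO in both lines, for the combination against IFNγ in MOLM13, and for the line differences with IFNγ and the combination stayed within 1.5 times under all settings but single libraries left out. They ran from 5157 to 7455 (MOLM13 IFNγ), 8940 to 10645 (MOLM13 combination), 2890 to 4317 (MOLM13 combination against IFNγ), 7709 to 10526 (MV411 IFNγ), 9639 to 11525 (MV411 combination), 2117 to 3193 and 4476 to 4964 (line differences). Scaling with DESeq2 size factors and the filter at 1 CPM moved no count beyond 1.5 times. Of the 437 list tests, 152 passed with the preset and 45 with an estimated correlation.

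With the replicate number as a block the MOLM13 counts were 3118 for decitabine, 88 for the decitabine by IFNγ interaction and 2 for the sgRNA by combination interaction. The MV411 counts with the block were 1443 for decitabine, 2487 for the combination against IFNγ and 122 for the decitabine by IFNγ interaction, and for the CIITA sgRNA 93 in DMSO, 84 with decitabine, 145 with IFNγ and 55 with the combination. Among the named genes the block changed 1 call, the line difference of HLA-DRA with decitabine (adjusted p = 0.0472), and no other. It changed 18 list calls at the preset correlation. In comparisons whose numbers pair, it added the progenitor list with decitabine in MOLM13 (adjusted p = 0.0172), class I (0.0496) and stress (0.0151) for the CIITA sgRNA in MOLM13 with DMSO, the inflammatory (0.0386) and monocyte (0.0251) lists there with IFNγ, processing (0.0185) with the combination, and the erythroid list (0.0372) in MV411 with DMSO. The 1 list call it ended was lymphoid with the combination in MV411 (0.0595).

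With no filter the counts in MOLM13 were 181 for the decitabine by IFNγ interaction, 40, 32, 64 and 59 for the CIITA sgRNA in DMSO, decitabine, IFNγ and combination, and 30 for the sgRNA by combination interaction. MV411 had 1193 for decitabine, 414 for the decitabine by IFNγ interaction, 341, 139, 334 and 136 for the CIITA sgRNA, and 94 for the sgRNA by combination interaction, and 917 for the line difference with decitabine. DESeq2 gave 63 for the MOLM13 decitabine by IFNγ interaction, 1 and 2 for the CIITA sgRNA in MOLM13 with DMSO and decitabine, 87 for the MV411 decitabine by IFNγ interaction, and 68, 41, 98 and 38 for the CIITA sgRNA in MV411. With only the groups compared in the fit, and so fewer libraries to estimate the spread, the CIITA sgRNA counts were 0, 6 and 21 in MOLM13 with decitabine, IFNγ and combination and 8 and 18 in MV411 with DMSO and IFNγ. The MV411 counts were then 686 for the combination against IFNγ and 26 for the decitabine by IFNγ interaction.

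With each library left out in turn, and so fewer samples, counts in MOLM13 ran from 1048 to 1769 for decitabine (1048 and 1325 without decitabine replicates 1 and 3), 1686 to 3206 for the combination against IFNγ (1686 and 1844 without IFNγ replicates 1 and 2, 1838 and 1839 without combination replicates 1 and 3), 0 to 1 for the CIITA sgRNA with decitabine (0 without CIITA sgRNA replicate 1 or 3 or control replicate 2) and 7 to 13 with IFNγ (7 without CIITA sgRNA replicate 1). In MV411 they ran from 348 to 499 for decitabine (348 and 420 without decitabine replicates 1 and 3, 450 and 372 without DMSO replicates 2 and 3) and 804 to 1258 for the combination against IFNγ (804 and 926 without combination replicates 2 and 3, 888 without IFNγ replicate 1). The MV411 decitabine by IFNγ interaction ran from 23 to 87 (23 and 25 without decitabine replicates 1 and 2, 87 and 32 without DMSO replicates 2 and 3, 31 without IFNγ replicate 1 or combination replicate 3). The CIITA sgRNA in MV411 ran from 10 to 65 in DMSO (10 without CIITA sgRNA replicate 1, 11 and 65 without control replicates 1 and 2), 15 to 82 with IFNγ (82, 15 and 21 without CIITA sgRNA replicates 1, 2 and 3, 23 and 26 without control replicates 1 and 2) and 12 to 18 with the combination (12 without CIITA sgRNA replicate 3). The MV411 sgRNA by combination interaction ran from 0 to 5 (1 without control combination replicate 3, 5 without control DMSO replicate 2), and the line difference with decitabine from 271 to 513 (271 without MOLM13 decitabine replicate 1, 284 without MV411 decitabine replicate 3).

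Of 248 named gene values, 0 changed direction outside the fits without a library. DESeq2 gave an adjusted p for 243, with 3 calls lost and 2 gained; the filter at 1 CPM kept 242, with 3 lost; 2 calls were gained with no filter, and 13 of 246 were lost with other libraries in the fit. HLA-DRA gained a call in MOLM13 with the CIITA sgRNA in DMSO (adjusted p = 1.5e-21 with no filter and 0.0149 with DESeq2) and lost it with decitabine (0.0569 with only the groups compared). From the same libraries its adjusted p in DMSO was 0.867 with edgeR and the filter. The CIITA sgRNA libraries there ran from 0.418 to 0.987 CPM. Values and counts with no filter are therefore not read as stronger evidence. Of 1758 values without a library, 166 lost a call and 2 gained 1, both for HLA-DRA in the line difference with decitabine. In 34 of the 166 the log2 fold change was as large or larger than with all libraries, and the lowest was 69.2% of it (median 94.1%). CYBB in the MV411 decitabine by IFNγ interaction and CD86 in the line difference with decitabine lost theirs in 10 of 12 such fits. In 10 values, all of genes not past the test, the direction turned. HLA-DRA in the MOLM13 decitabine by IFNγ interaction stood at 0.18 without decitabine replicate 2 and 0.08 without IFNγ replicate 3 (from -0.25 to 0.18). CIITA under the CIITA sgRNA in MOLM13 stood at 0.00 with decitabine without CIITA sgRNA replicate 3 (from -0.06 to 0.00), and with IFNγ at -0.05 without CIITA sgRNA replicate 3 and -0.02 and -0.03 without control replicates 1 and 2 (from -0.05 to 0.09). CIITA in the MV411 decitabine by IFNγ interaction stood at 0.01 without decitabine replicate 2, 0.00 without combination replicate 2, 0.03 without DMSO replicate 1 and 0.04 without IFNγ replicate 3 (from -0.04 to 0.04). Depth limits the class II genes of MOLM13 in DMSO, where HLA-DQA1 had 2 counts over the group and HLA-DRB6 had 0.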

Other observations

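The tests in this part were chosen after the results above were seen, except that of silent genes. In cells with the CIITA sgRNA the class II genes still rose with IFNγ. HLA-DRA rose by 5.81 ± 0.24 in MOLM13 (log2 fold change, edgeR adjusted p = 4.7e-17) and by 1.81 ± 0.10 in MV411 (adjusted p = 1.7e-14). The class II list had 12 of 12 genes higher in MOLM13 (median 4.60, adjusted p = 0.000215 with an estimated correlation) and 11 of 12 in MV411 (median 1.75, adjusted p = 5.9e-07 with an estimated correlation). With the combination against IFNγ HLA-DRA was higher by 1.03 ± 0.15 (adjusted p = 2.2e-05) and 0.59 ± 0.09 (adjusted p = 0.000113), and the class II medians were 1.06 (adjusted p = 0.0324 with an estimated correlation) and 0.49 (adjusted p = 0.000151 with an estimated correlation). CIITA rose by 2.42 ± 0.07 with IFNγ in MOLM13 and by 1.25 ± 0.05 in MV411.

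The type I interferon genes fell with decitabine in these cells, for 28 of 35 in MOLM13 (adjusted p = 0.000408 with an estimated correlation) and 14 of 35 in MV411 (adjusted p = 0.0493 with an estimated correlation). For some other lists in these cells the adjusted p with an estimated correlation is given, and beside it that of the same test in the control sgRNA cells and in the other line; differences between the sgRNAs in these effects were not tested. With the combination against IFNγ in MOLM13, monocyte genes were higher for 19 of 25 (median 0.80, adjusted p = 0.0324), against 13 of 25 in control sgRNA cells (0.112) and 4 higher and 1 lower of 22 in MV411 (0.2). With decitabine they were higher for 4 of 22 in MV411 (median 0.25, adjusted p = 0.0178; control sgRNA 0.0801), and for 13 with 2 lower in MOLM13 (0.0545). With the combination against IFNγ in MV411, cell cycle genes were higher for 27 of 36 and lower for 0 (median 0.28, adjusted p = 0.017), against 6 higher in control sgRNA cells (0.0805) and, in MOLM13, 0 higher and 3 lower (median -0.14, adjusted p = 0.684). Progenitor and granule genes were higher there for 7 of 17 and lower for 0 (adjusted p = 0.0174; control sgRNA 0.0805, MOLM13 0.641), while with IFNγ they were lower for 10 and higher for 1 (median -0.26, adjusted p = 0.0417; control sgRNA 0.0717, MOLM13 0.2). Methylation machinery genes were higher for 3 and lower for 1 of 16 with the combination against IFNγ (adjusted p = 0.0395; control sgRNA 0.0805, MOLM13 0.506). With decitabine in MV411 p53 targets were higher for 3 of 30 (median 0.18, adjusted p = 0.0493; control sgRNA 0.148, MOLM13 0.0545) and class II genes for 2 of 12 (median 0.21, adjusted p = 0.0165; control sgRNA 0.0226, MOLM13 0.314). In all, decitabine raised 1340 and lowered 1015 genes in the CIITA sgRNA cells of MOLM13, and 237 and 92 in those of MV411.

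One hypothesis was that decitabine switches on silent genes. It would be in line with more genes going from at most 1 count over the 3 DMSO libraries to 20 or more over the 3 decitabine libraries than the other way, by over 3 times. In the control sgRNA cells 4 genes did so in MOLM13 against 1 the other way, and 2 in MV411 against 0. The numbers are small, and the CIITA sgRNA cells had 4 against 1 in MOLM13 and 6 against 1 in MV411. In MOLM13 0 of these genes were shared between the sgRNAs, and in MV411 both were: MAGEA4, from 0 to 56 counts and from 0 to 89, and the interleukin receptor IL23R, from 1 to 34 and from 0 to 24, which was named after its values were seen. Between the lines 0 of these genes were shared in the control sgRNA cells, and 0 in the CIITA sgRNA cells.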
